A study of Mus musculus with 7 samples.

How the data were processed

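The data were ATAC-seq peak lists from 7 mouse samples, 1 per group. ATAC-seq marks open chromatin by the sites at which the Tn5 transposase inserts sequencing adapters. Per the labels, 3 samples were female lines from a 129S1 x Cast cross: embryonic stem cells (mESC), wild-type neural progenitor cells (NPC) and NPC with the deltaFT deletion. The other 4 were male mESC (TXY) with a doxycycline-inducible Xist at its endogenous locus, either intact or lacking the A repeat (deltaRepA), each without doxycycline (no dox) or with 2 ug/mL for 48 hours (plus dox). Per the labels, each replicate used 50K cells and was sequenced as paired reads of 75 bp. The source label of the mESC sample reads as neural progenitors, while its title and growth conditions are those of mESC, and the title was followed. The description of both plus-dox samples names a no-dox file, and the titles were followed there too.

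Per the submitters' processing notes, the tools were cutadapt, Bowtie2 and MACS2 and the build was mm9. Versions, settings, the handling of duplicate reads, any shift of reads to the Tn5 insertion site and the way reads were given to alleles are not given in the sources used here. For each female line the authors deposited a list of peaks reproducible between its 2 libraries (IDR list, irreproducible discovery rate under 0.05 in every row) and 1 list per library. For each TXY condition they deposited 1 list from merged libraries, so these have no replicate check. The IDR lists deposited by the authors hold a raw read count per peak and the count given to each allele. Whether the counts cover 1 library or both is not given in the sources used here. The allele columns carry no strain name, so the alleles are called first-listed and second-listed. In the library and TXY lists, the deposited fold enrichment (a ratio over local background) and −log10 p and q values are the authors' MACS2 values. They were used to rank, filter or match peaks within a list and were not compared between lists.

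Each file was tested before use. In the library lists chrX peaks carried their own name prefix and were weaker than autosomal peaks, with a median −log10 p of 5.44 against 6.88 in mESC library 1. In both NPC lines the chrX rows of library 2 were identical to those of library 1, all 7114 in wild type and all 6657 in deltaFT, while no autosomal row was shared. Of the library 2 values that the IDR list of wild-type NPC gives for chrX peaks, 51.5% were found in the library 2 list, against 94.2% for autosomal peaks; in deltaFT NPC it was 52.6% and 91.6%. Library 2 of the NPC lines therefore gave no separate chrX measurement, and the spread between libraries was taken from autosomes. The IDR lists also held chrX peaks with few reads: 8.37% of chrX peaks in wild-type NPC had fewer than 20 reads, against 0.00504% of autosomal peaks. The share was 9.56% in deltaFT NPC and 7.96% in mESC.

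Peak sets were compared by overlap of at least 1 bp with bedtools 2.31.1 after joining touching intervals, which joined 1 pair in the mESC IDR list, 2 in the deltaFT IDR list and none elsewhere. Tables were computed with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and drawn with matplotlib 3.10.9. Shares carry exact Clopper-Pearson 95% intervals. Ratios of peak counts were divided by the ratio over the 19 autosomes and carry 95% intervals from the normal approximation on the log scale. All intervals cover counting error alone, since reads without molecular identifiers are not independent molecules and each group is 1 sample. No p-value was computed between groups. The 19 autosomes of the same lists served as the background for chrX.

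Allelic shares used peaks with at least 10 allelic reads. A peak counted as read from both alleles where each allele held at least 20% of them. Peaks of 2 lines were matched to the peak of largest overlap. For the TXY lists, the share of no-dox peaks also found with dox was computed per chromosome, and again after weighting each chromosome to the strengths of the chrX peaks in 10 bins of −log10 p. The steps were tested on simulated data. A simulated loss of -15.0 points on chrX was recovered as -14.8 points over the 139786 TXY wild-type peaks and as -13.7 points over the 129021 deltaRepA peaks, and simulations without loss gave 0.272 and 0.869 points. In simulated counts for the 833 wild-type NPC peaks, 98.6% of peaks made with both alleles were called so, and in those for the 754 deltaFT peaks 98.0%. Simulated peaks had either equal alleles or almost no first-allele reads. The simulation therefore does not show how well peaks near the 20% limit were classed.

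The comparisons of peak overlap, of chrX peak counts and of peaks kept with dox, and the share of chrX allelic reads, were fixed before the data were examined, with their alternatives. Allelic reads were to be given for the 129S1 allele, which the columns did not allow. The classes of peaks read from both alleles, the peaks matched between lines, the 1 Mb windows, the runs of missing peaks, the classes of peak strength, the 20 Mb stretches, the fates of peaks in both no-dox lists and the 5 Mb autosomal segments were added after the data had been seen. The criterion for a loss of first-allele copies on chromosome 12 was at first set on first-allele reads alone, and a criterion on all reads was added after its outcome was known; both outcomes are given.

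The fixed rule named genes: members of gene lists, and genes with the highest authors' score among peaks particular to a list. Gene annotation of the mm9 build was not used here and coordinates were not converted, so the rule could not be run on genes. It was applied to peaks instead, a change made after the files were seen. For each comparison of female lines and each direction it gave the 10 peaks with the highest score that overlapped no peak in the IDR list or library lists of the other line, the score being the lower of the −log10 p values of the 2 libraries. For each TXY genotype it gave the 10 strongest chrX no-dox peaks lost and the 10 strongest kept. Peaks are named by mm9 position. The fixed gene lists, and peaks around Dxz4, Firre and Xist by name, were not analysed here, and peaks were not assigned to genes, exons or promoters.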

Results

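Open chromatin was measured in 7 samples, 1 per group. The female mESC IDR list held 28907 peaks with 6490181 reads in them, the wild-type NPC list 41126 peaks with 11014387 reads and the deltaFT NPC list 37270 peaks with 11085592 reads. Reads assigned to an allele made up 39.6%, 38.5% and 40.4% of these. The TXY lists held 139825 peaks for wild type without dox, 125498 with dox, 129055 for deltaRepA without dox and 142526 with dox. The male lists held 34 to 40 chrY peaks each and the female IDR lists none.

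The first comparison asked which open sites differ between stem cells and neural progenitors. Of the mESC peaks, 13222 of 28906, or 45.7% (95% interval 45.2% to 46.3%), overlapped a peak of the wild-type NPC IDR list. Of the wild-type NPC peaks, 31.8% (31.4% to 32.3%) overlapped a peak of the mESC IDR list. Library lists of the same line overlapped more, by 64.3% to 70.8% in mESC and 70.0% to 82.2% in wild-type NPC, whereas mESC library lists overlapped those of wild-type NPC by 36.2% to 41.4%. The difference between cell types was thus larger than the spread between libraries.

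Of the mESC peaks, 12035 (41.6%) overlapped no peak in any wild-type NPC list, and of the wild-type NPC peaks 21478 (52.2%) overlapped none in any mESC list. The strongest mESC-specific peak lay on chromosome 2 at 176858397 to 176859222 with 1743 reads, followed by chromosome 4 at 146034367 to 146035348 with 1860 reads. Chromosome 4 held 2 more of the 10 named mESC-specific peaks, at 146649154 to 146649990 and 145053455 to 145054276. The strongest NPC-specific peaks lay on chromosome 15 at 71849104 to 71849848 with 1479 reads and on chromosome 2 at 80691250 to 80691875 with 1791 reads. None of the 20 named peaks was on chrX.

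Female mESC carry a pair of active X chromosomes, and NPC have inactivated either of them, so chrX was set against the autosomes. From mESC to wild-type NPC the number of autosomal peaks rose by 44.1%, and that of chrX peaks by 4.75%. The chrX ratio relative to autosomes was 0.727 (0.674 to 0.784), the lowest of 20 chromosomes, next to an autosomal range of 0.740 to 1.16. The lowest autosome was chromosome 12, part of which had more reads in mESC, as described below. Chromosome 11 followed at 0.825. The chrX ratio was 0.723 among peaks with at least 20 reads. In library 1 alone it was 0.944.

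The alleles of chrX were balanced in mESC and unequal in both NPC lines. The first-listed allele held 48.8% (48.5% to 49.2%) of chrX allelic reads in mESC, 21.3% (21.0% to 21.6%) in wild-type NPC and 8.29% (8.08% to 8.51%) in deltaFT NPC. These shares rest on 905, 833 and 754 peaks. Over all autosomes the same allele held 47.9%, 50.4% and 48.9%. Single autosomes ranged from 43.6% to 57.6% in wild-type NPC, from 44.7% to 52.3% in deltaFT NPC and from 30.4%, on chromosome 12, to 51.1% in mESC. The first-listed X was therefore the less accessible X in both NPC lines.

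**Figure D1:**
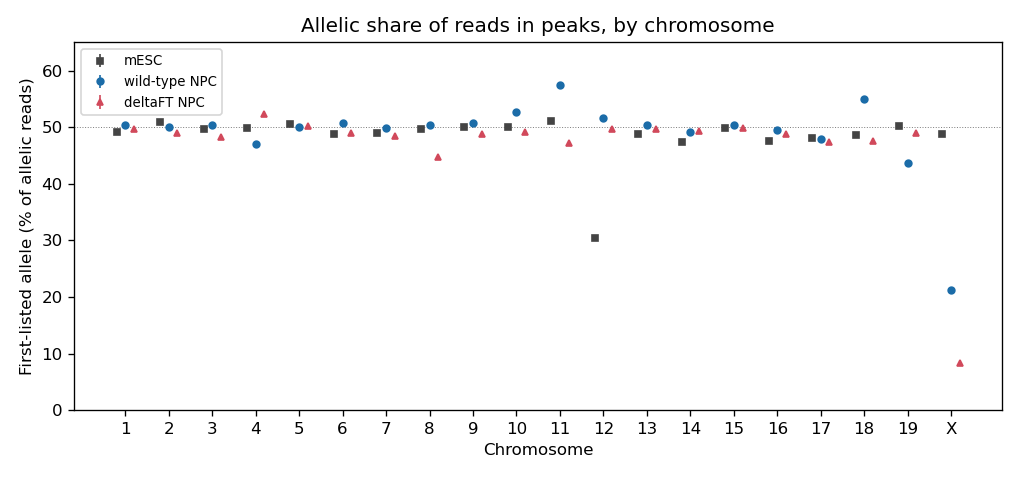
Share of allelic reads from the first-listed allele (percent, y axis) on each chromosome (x axis) in mESC, wild-type NPC and deltaFT NPC. Points are pooled reads in peaks with 95% intervals, which are smaller than most symbols; chrX falls to 21.3% in wild-type and 8.29% in deltaFT NPC, and chromosome 12 lies at 30.4% in mESC.

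Most chrX peaks in wild-type NPC came almost entirely from the second-listed X, while a sizeable minority was open on both. Of 833 peaks, 463 (55.6%) had under 5% first-allele reads and 221 (26.5%, 23.6% to 29.7%) were read from both alleles. In deltaFT NPC 76 of 754 (10.1%, 8.02% to 12.5%) were read from both, and in mESC 857 of 905 (94.7%). With at least 10% of reads asked of each allele the share was 34.8% in wild-type NPC and 24.0% in deltaFT. With 30% it was 19.9% and 5.84%, so the size of the contrast depended on the limit. The median peak hardly differed between the NPC lines, at 3.26% first-allele reads in wild type and 3.77% in deltaFT.

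The comparison of wild-type with deltaFT NPC asked what removal of the boundary region between the large domains of the inactive X, which holds the Dxz4 macrosatellite, changes in accessibility. Regions open on both X chromosomes in wild-type NPC were mostly open on a single X in the deltaFT line. Among 499 chrX peaks with enough allelic reads in both lines, 137 were read from both alleles in wild type; 34 of these were still so in deltaFT, and 68 had under 5% first-allele reads. In the other direction, 14 of the 362 peaks not read from both alleles in wild type were so in deltaFT. For the 137 peaks the median first-allele share was 43.9% in wild type and 5.10% in deltaFT, and the pooled share 44.7% and 14.95%. In 101 of the 499 peaks (20.2%) the deltaFT interval lay below the wild-type interval and in 16 (3.21%) above it, compared with 6.36% and 3.80% of 21433 autosomal peaks.

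The same was seen by position. Windows of 1 Mb with at least 5 usable peaks in each NPC line numbered 61. Of these, 20 had a first-allele share of at least 20% in wild type, and 3 of the 20 did in deltaFT. In 17 of the 20 the deltaFT interval lay below the wild-type interval, and in 13 the deltaFT share was under 10%. At 91 to 92 Mb the share crossed 20% with overlapping intervals, 20.3% (18.3% to 22.3%) in wild type and 17.6% (15.9% to 19.5%) in deltaFT. Windows pool all usable peaks of a line, so their peaks can differ: 47 to 48 Mb held 15 in wild type and 6 in deltaFT. Over all windows 4 reached 20% in deltaFT, among them 104 to 105 Mb, which went the other way. There the share was 6.90% (3.61% to 11.7%) in wild type and 31.8% (23.3% to 41.4%) in deltaFT, on 174 and 110 reads. At 160 to 161 Mb the share was 47.6% (46.0% to 49.1%) in wild type and 3.73% (2.91% to 4.71%) in deltaFT. At 71 to 72 Mb it was 44.8% and 2.86%, and at 162 to 163 Mb 51.1% and 7.18%. At 100 to 101 Mb the share was 37.4% (34.5% to 40.4%) in wild type and 39.6% (36.7% to 42.6%) in deltaFT. At 17 to 18 Mb it was 20.2% and 27.6%, which rested mainly on the peak at 17739048 to 17740016, with 172 first-allele reads in wild type and 199 in deltaFT. In the 28 windows with under 5% in wild type, the median share was 1.57% in wild type and 3.63% in deltaFT.

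**Figure D2:**
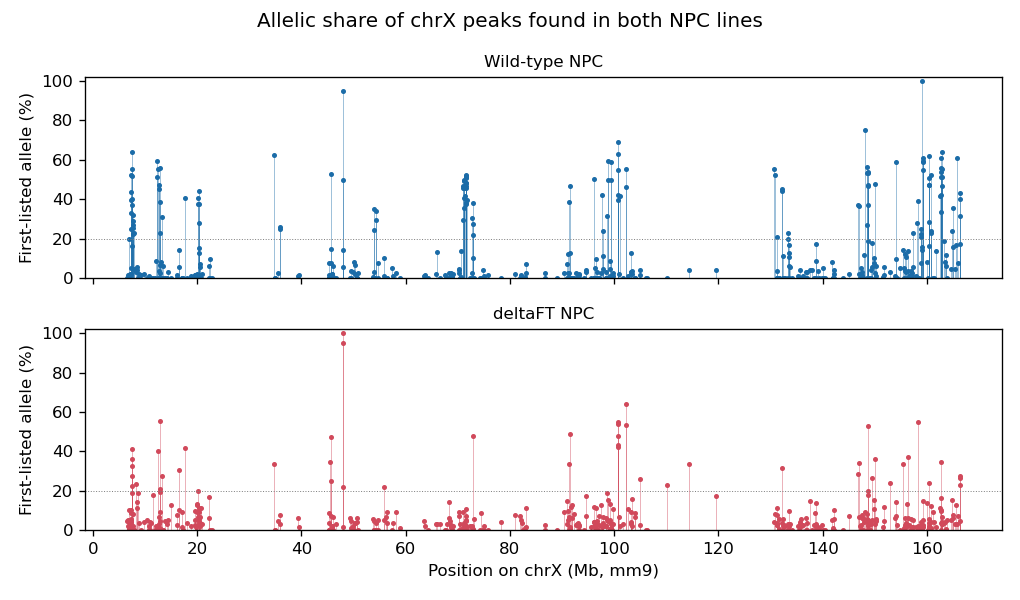
First-listed allele share (percent, y axis) of 499 chrX peaks matched between the NPC lines, by mm9 position in Mb (x axis); each point is a peak and the dotted line marks 20%. Of 137 peaks read from both alleles in wild-type NPC, 34 were so in deltaFT NPC.

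Single peaks showed the same contrast; those named here were chosen after their values were seen, as the peaks with most allelic reads in each class. The peak at 160857303 to 160858188 had 595 first-allele and 545 second-allele reads in wild type, and 17 and 404 in deltaFT. The peak at 160346383 to 160347361 went from 50.6% to 3.78% first-allele reads, and that at 165757895 to 165758787 from 60.9% to 2.90%. By contrast, the peak at 146912332 to 146913257 had 36.8% (33.4% to 40.2%) in wild type and 34.1% (30.6% to 37.8%) in deltaFT. The peak at 91422949 to 91423654 had 38.6% (34.4% to 42.9%) and 33.8% (29.7% to 38.0%), and that at 45609607 to 45610247 had 52.8% and 47.3%, with overlapping intervals.

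Peaks of the wild-type list were also missing from a short stretch of chrX in deltaFT NPC. Of 1434 chrX peaks, 264 (18.4%) overlapped no peak in the IDR list or library lists of deltaFT, next to 10.6% of autosomal peaks. The 2 deltaFT library lists had the same chrX rows, so on chrX they gave 1 check and not 2. These 264 peaks were weak, with a median of 27 reads against 146 for the others. Among 13 runs of at least 3 neighbouring missing peaks, the longest had 18 peaks but 59 reads in all. The run with most reads, 685 in 3 peaks, lay at 72989838 to 72996020; it was chosen after its values were seen. Its reads were 302 from the first-listed and 2 from the second-listed allele. Its strongest peak, at 72995729 to 72996020, had 224 and 2 in wild-type NPC, and an overlapping mESC peak 212 and 2, so its allelic imbalance was not particular to cells with an inactive X. Nearby, the peak at 72919135 to 72920004 had 158 first-allele reads in wild type and 2 in deltaFT, with 574 and 471 from the second-listed allele. The coordinates of the deltaFT deletion were not used here, so whether these peaks lay in deleted sequence or in chromatin that was closed was not tested.

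**Figure D3:**
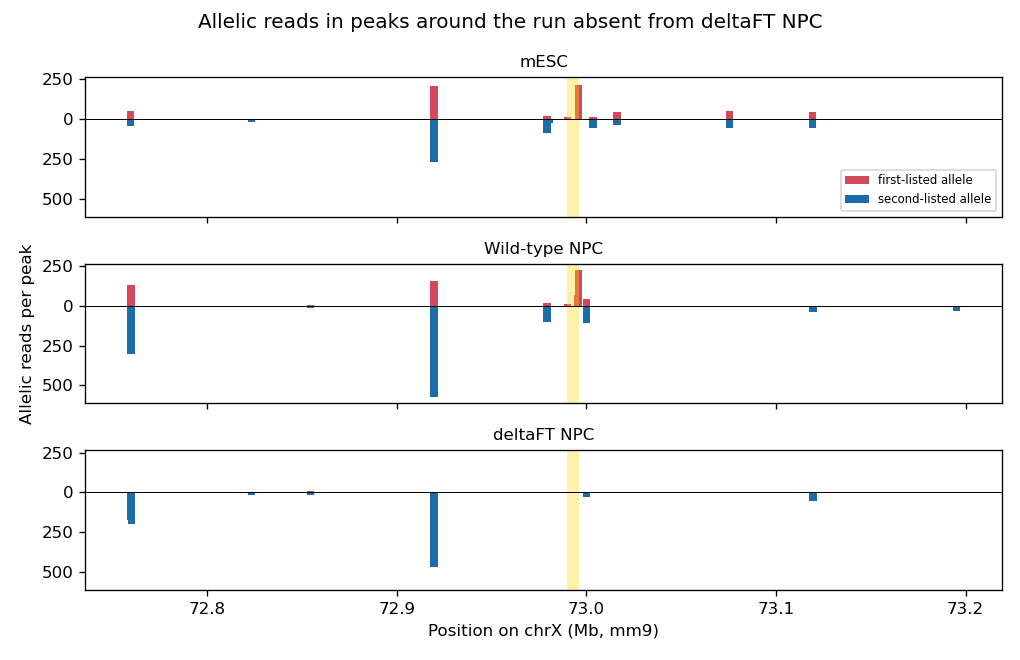
Allelic reads per peak (y axis, first-listed allele upwards and second-listed downwards) by mm9 position on chrX in Mb (x axis) in mESC, wild-type NPC and deltaFT NPC; bar widths are not to scale. The shaded stretch, 72989838 to 72996020, holds 302 first-allele reads in wild-type NPC and no peak in deltaFT NPC.

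Most peaks were found in both NPC lines, with a lower share on chrX. Of the wild-type NPC peaks 65.5% (65.1% to 66.0%) overlapped a deltaFT peak, and of the deltaFT peaks 71.8% a wild-type peak. On chrX these shares were 53.9% and 62.0%. They were not adjusted for peak strength, and peaks with few reads were more common on chrX than on autosomes. Library lists of wild type overlapped those of deltaFT by 58.2% to 69.5%, and those of deltaFT overlapped those of wild type by 65.7% to 77.7%. Library lists of the same line overlapped by 70.0% to 82.2% in wild type and 69.4% to 84.0% in deltaFT. Wild-type lists thus overlapped deltaFT lists less than each other, while in the other direction the ranges between and within lines overlapped. The chrX ratio of peak counts, deltaFT over wild type and relative to autosomes, was 0.948 (0.877 to 1.02), within the autosomal range of 0.865 to 1.19. Reads per bp in matched chrX peaks differed by a median log2 of -0.19, next to -0.15 to 0.14 on the autosomes. Wild-type peaks absent from all deltaFT lists numbered 4456 (10.8%), led by chromosome 10 at 81703528 to 81704318 with 675 reads. Peaks particular to deltaFT numbered 2192 (5.88%), led by chromosome 1 at 123373440 to 123374131 with 785 reads. Of the 10 named deltaFT peaks 3 were on chrX, against 0 of 10 in the other direction. Over the full list 264 of the 4456 absent wild-type peaks were on chrX. On the autosomes alone 10.6% of wild-type and 5.53% of deltaFT peaks were absent, each below the share over all chromosomes. The named peaks are too few to show a difference between the lines on chrX. These overlaps compare 1 line with 1 line.

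In male TXY cells the question was whether induced Xist RNA closes chromatin on the single X, and whether this needs its A repeat, the part known to be required for gene silencing. With dox the TXY wild-type cells lost chrX peaks beyond the autosomes. The number of chrX peaks went from 2377 to 1462, a change of -38.5%, while autosomal peaks changed by -9.76%. The chrX ratio relative to autosomes was 0.682 (0.638 to 0.728), next to an autosomal range of 0.962 to 1.06. Of the no-dox chrX peaks 1320 (55.5%, 53.5% to 57.5%) were also found with dox, -8.76 points from the autosomal median of 64.3%. Among the autosomes chromosome 1 kept fewer, 54.2%. At equal peak strength the gap was -16.9 points and chrX was the lowest of 20 chromosomes, with autosomes between 70.4% and 73.9%.

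The loss was measurable among weak and middling chrX peaks. Of the chrX peaks with a −log10 p from 5 to 10, 37.0% were kept, next to 66.4% of such autosomal peaks; from 10 to 20 it was 84.7% and 96.4%. From 20 to 40 it was 98.6% and 99.9%, and at 40 or more all 172 chrX peaks and all 5387 autosomal peaks were kept, so presence in a list could not show a loss among the strongest peaks. The strongest lost peaks lay at 164092776 to 164093267, 103675176 to 103675549 and 99137736 to 99138171; 9 of the 10 named lost peaks were present in both deltaRepA lists. The strongest kept peaks lay at 103381995 to 103382619 and 161418019 to 161418807. Along chrX, stretches of 20 Mb fell short of the share expected from peak strength by between -7.19 points at 0 to 20 Mb and -22.6 points at 80 to 100 Mb. Of the wild-type plus-dox chrX peaks 7.52% were new and 92.5% were found without dox; on the autosomes the median found without dox was 69.8%, and chrX was the highest of 20 chromosomes.

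**Figure D4:**
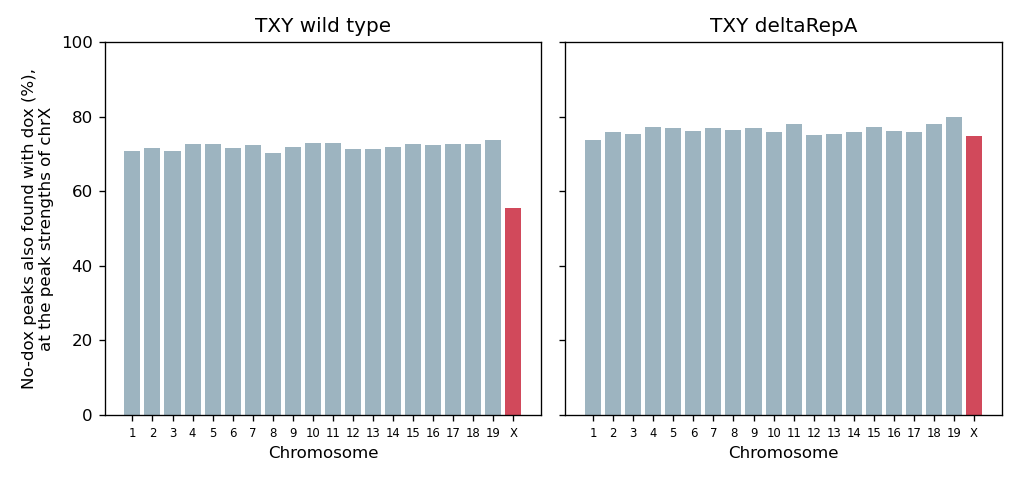
Percent of no-dox peaks also found with dox (y axis) on each chromosome (x axis), weighted to the peak strengths of chrX, for TXY wild type and deltaRepA; chrX is in red. In wild type chrX stands at 55.5% with autosomes from 70.4% to 73.9%; in deltaRepA it stands at 1877 of 2504 peaks with autosomes from 73.9% to 79.9%.

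Without the A repeat, chrX lost a smaller share of its peaks with dox, but still had fewer peaks relative to autosomes. The deltaRepA lists held 2504 chrX peaks without dox and 2442 with dox, a change of -2.48%, while autosomal peaks changed by 10.7%. The chrX ratio relative to autosomes was 0.881 (0.833 to 0.932), the lowest of 20 chromosomes and below the autosomal range of 0.961 to 1.05. Of the plus-dox chrX peaks 22.1% were new and 77.9% were found without dox, next to an autosomal median of 63.1%. A higher share on chrX was also seen without dox. Of the wild-type no-dox peaks, 1806 of 2377 on chrX overlapped a deltaRepA no-dox peak (95% interval 74.2% to 77.7%), next to an autosomal median of 63.1%. In the other direction the share was 72.9% against 66.3%. At equal peak strength chrX stood 5.25 and -0.383 points from the autosomal median. For plus-dox peaks found without dox it stood 6.74 points above that median in deltaRepA and 13.9 in wild type, each the highest of 20 chromosomes. A higher share on chrX was thus not particular to dox, but between the no-dox lists at equal strength it depended on the direction. Of the no-dox chrX peaks 1877 (95% interval 73.2% to 76.6%) were also found with dox, 5.52 points from the autosomal median of 69.4%. At equal peak strength the value was -1.36 points, second lowest of 20 chromosomes, and with peaks of −log10 q of at least 5 it was -2.52 points. With both together it was -4.20 points, and chrX was the lowest of 20 chromosomes. The direction of the deltaRepA value thus depended on the peaks compared. At equal peak strength the autosomes had a standard deviation of 1.34 points, a spread as large as the -1.36 points found. Simulated deltaRepA lists without loss gave 0.869 points. In them keeping depended on peak strength alone, without other differences between chromosomes, so they do not show whether the -1.36 points are a loss.

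The wild-type value minus the deltaRepA value was -14.3 points, and the same difference for the autosomes ranged from -7.84 to 1.01 points. At equal peak strength it was -15.5 points against -2.17 to 0.990. Among 1806 chrX peaks of the wild-type list that were present in both genotypes without dox, 422 were lost with dox in wild type but not deltaRepA and 48 in deltaRepA but not wild type. The corresponding autosomal numbers were 9358 and 5739 of 82996. Each condition was 1 merged list, so the difference has no replicate check.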

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

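The test of depth and peak strength in this part, and the stricter threshold at equal strength, were chosen after the result was seen. The share of chrX peaks kept with dox, relative to the autosomal median, was -8.76 points in TXY wild type and 5.52 points in TXY deltaRepA. These 2 values stood out because the genotypes moved in opposite directions. The difference was not tested, since each condition is 1 list, and at equal peak strength deltaRepA stood at -1.36 points, or -4.20 points with −log10 q of at least 5, so the opposite direction does not hold there.

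The lower value in TXY wild type was weighed against a lower depth of the plus-dox list or weaker chrX peaks. Either would lower autosomal peaks of the same strength as much, but chrX kept 55.5% while the lowest autosome kept 70.4%, which argues against both. Whether the loss was even across classes of chrX peaks stays open. By position, the shortfall ran from -7.19 to -22.6 points between stretches of 20 Mb, a spread that was not tested. Peaks that wild-type NPC read from both alleles differed from the others by -0.426 points in the share kept at a given strength (149 and 273 peaks). A permutation test over 422 rotations of the classes along the chromosome gave p = 0.882, which does not show that they are alike. Their median −log10 p was 19.4 and 23.3, near the range where presence in a list could not show a loss. A candidate explanation is closing of chromatin by Xist that is larger with the A repeat, as a hypothesis from 1 list per condition. In deltaRepA the chrX ratio relative to autosomes was also the lowest of 20 chromosomes, at 0.881. A difference between clones or cultures of the genotypes was not tested.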

How the results depend on the processing

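For chrX allelic shares, the median over peaks, leaving out the 10 peaks with most reads and peaks in both NPC lists were added after seeing the data, as were all settings for peaks read from both alleles, the minimum of 20 reads per peak for chrX ratios, and the stricter q at equal score. Of 62 alternative values 29 stayed within the interval of the main value (1 SD over autosomes for the difference between genotypes), 30 moved outside it and 3 changed sign. The cause was not tested unless given.

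Asking for 50% of a peak covered gave 42.9% for mESC peaks shared with wild-type NPC and 63.3% for wild-type NPC peaks shared with deltaFT, and a reciprocal 50% gave 36.7% and 58.0%. Peaks in both library lists, autosomes alone, gave 44.9% and 68.2%. Without either replicate the values were 36.2% to 41.4% and 58.2% to 69.5%. The chrX ratio of wild-type NPC to mESC was 0.944 without replicate 2.

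For TXY wild type the chrX value was -15.1 points with −log10 q of at least 5, -13.7 with peaks of both no-dox lists, -16.9 with autosomes matched on score and -18.1 with that q and score together. For deltaRepA it was -2.52, 2.29, -1.36 and -4.20, and 7.31 with reciprocal overlap. The difference between genotypes kept its direction and stayed between -12.5 and -16.2 points.

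The chrX first-allele share in wild-type NPC was 21.6% with at least 20 reads, 3.26% as a median over peaks, 19.5% without the 10 peaks with most reads and 21.9% over peaks in both NPC lists. In deltaFT NPC the last 3 were 3.77%, 6.85% and 7.92%. With at least 10% from each allele, 98.5% of mESC, 34.8% of wild-type NPC and 24.0% of deltaFT peaks were read from both; with 30% it was 86.2%, 19.9% and 5.84%.

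No paired analysis was possible because each group is 1 sample; the no-dox and plus-dox lists of each TXY genotype were compared directly, as a single pair without replicates. Not run were gene lists and splits into distal and start peaks (no mm9 annotation used), −log10 q of at least 5 for the chrX ratios (no q in the IDR lists), and chrX ratios from library 2 or both libraries (chrX rows copied in the NPC lines). Leaving TXY intervals unmerged changed nothing, since none overlapped.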

Other observations

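All tests in this part were chosen after the result was seen, except that of a difference between clones. A peak present in deltaFT but in no wild-type NPC list, on chrX at 120216750 to 120217520, was read almost entirely from the less accessible X, with 273 first-allele and 4 second-allele reads (98.6%, 96.3% to 99.6%). Its absence from wild type was checked against 1 set of chrX library rows, since the 2 library lists shared them. The overlapping mESC peak had 81 and 48. Autosomes also had segments of 5 Mb with unequal alleles (median peak under 40% or over 60%): 14 in deltaFT NPC, such as chromosome 11 at 85 to 90 Mb with 31.2% first-allele reads and chromosome 8 at 70 to 75 Mb with 32.3%, and 11 in wild-type NPC, such as chromosome 11 at 50 to 55 Mb with 63.1%.

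The lower first-allele share on chrX in deltaFT NPC was weighed against 3 explanations. Cells with the other X inactive, mixed into the wild-type NPC, would raise every chrX peak, but 55.5% of 674 wild-type peaks with at least 20 allelic reads lay under 5%. Loss of the less accessible X from part of the deltaFT cells would lower all peaks by a common factor. Of 137 peaks read from both alleles in wild type, however, 21 lay above the common factor on the odds (0.217) and 48 below it. Among the same 137 peaks, and not in addition to these, 29 were read from both alleles in both lines with overlapping intervals. That count bears on the question less, since some of these peaks had few reads and wide intervals. A difference between clones that does not come from the deletion cannot be told apart from an effect of the deletion, since there was 1 line per genotype. An effect of the deletion on regions open on the inactive X is therefore a hypothesis, and testing it needs more than 1 line per genotype.

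In mESC distal chromosome 12 was unequal, where first-allele reads made up 24.8% to 25.2% (95% interval) over 1050 peaks from 75 to 125 Mb. Read assignment that favours the second allele there would also show in the NPC lines, which had 50.3% and 49.1%. Second-allele reads rose by 1.32 and 1.38 (log2) against wild-type and deltaFT NPC, relative to other autosomes, so a gain of second-allele copies is a candidate explanation; the groups of the study name no biological one. Loss of first-allele copies stays open: first-allele reads changed by -0.14 (-0.32 to 0.00) and -0.12 (-0.21 to -0.02), and the first of these intervals reaches the bound of -0.3 set for it. Loss alone would not raise all reads, which rose by 0.69 and 0.76, but this criterion was added once the former had left the question open.

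In the TXY lists, the ratio of peak counts of wild type to deltaRepA, divided by the ratio over all 19 autosomes, was 1.51 on chromosome 8 without dox and 1.47 with dox. On chromosome 19 it was 1.32 and 1.43, and on chromosome 12 it was 0.756 and 0.783.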
